A study of Mus musculus with 8 samples.

How the data were processed

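The samples were nucleus accumbens RNA from male mice that had gone through a short conditioned place preference procedure, in which an animal learns to associate a place with an injection. Per the labels, 1 treatment was cocaine at 15 mg per kg on days 2, 3 and 4 of the procedure and the other was saline on the same days. RNA aliquots of 75 ng were amplified and labelled with Cy5 or Cy3 and hybridised to 2-colour whole-genome arrays, with 1 cocaine mouse set against 1 saline mouse on each array. The cocaine sample carried Cy5 in 2 hybridisations (group cocaine in Cy5, replicates 1 and 2) and Cy3 in the other 2 (group saline in Cy5, replicates 1 and 2). Each hybridisation was scanned on an Axon GenePix 4000B and on an Agilent G6525 scanner, which gave 8 scans. The 2 scans of a hybridisation are the same labelled RNA, so their mean was used as 1 replicate and n was 4 pairs of mice. The design text speaks of 5 measurements, and 4 hybridisations were analysed here.

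The deposited values are log2 ratios of the 2 channels, 44290 rows per scan. The image analysis, the background correction and any normalization are not given in the sources used here. The log base was read from the values, many of which lie at the log2 of simple fractions. Between 4 and 37 rows per scan held a stop value of 16.61 or -16.61 and were treated as missing. Column medians lay between -0.885 and -0.617 in the cocaine in Cy5 scans and between 0.637 and 0.823 in the saline in Cy5 scans, and Agilent scans of opposite orientation correlated at r between -0.964 and -0.894 across rows. The values were therefore treated as not normalized between dyes.

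The direction of the ratios was tested before any comparison. A scanner difference belongs to the dyes and not to the mice. Across rows, the Axon minus Agilent difference correlated at 0.514 and 0.517 between hybridisations of the same orientation, and at -0.542 to -0.492 between hybridisations of opposite orientation, so the columns had already been turned to a single treatment direction. That this direction is cocaine over saline is likely but is not stated in the labels. It rests on the cocaine in Cy5 columns being the unturned ones, read as channel 1 over channel 2, with channel 1 named first in each title.

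The platform annotation lists probes by feature number, and the rows of the deposited table do not follow that order. Read row by row, probes of the same accession correlated at r = -0.009 over 7325 pairs. Of 144 grid layouts tested, a staggered grid of 430 rows and 103 columns, read columns first and reversed, gave r = 0.513, and r = 0.934 over 364 pairs of spots of the 38 accessions spotted at least 10 times. The other layouts gave r between -0.025 and 0.029 over the same-accession pairs. This layout was chosen from the data by that test, and every gene name rests on it. With it, 32042 rows had 1 gene symbol, 47 had several and were not named, and 12201 had none. Rows without a symbol include the control spots, which the design text counts as 2756 and which could not be told apart here. Of the named probes, 31906 matched the gene table by gene identifier and 0 symbols needed an update. No genome build was given, so no coordinates are printed.

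Each scan was centred on its median, probes with 1 symbol were averaged per symbol, and the 2 scans of each hybridisation were averaged. A gene needed a value in at least 1 scan of each hybridisation, which left 31334 genes (19087 with a symbol, the others single probes). The log2 ratios were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with a cocaine coefficient and a dye coefficient, with 2 residual degrees of freedom, and Benjamini-Hochberg adjusted p below 0.05 was called, two-sided. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. The centring, fit, thresholds, 21 gene lists (433 of 480 entries measured) and the rule for named genes were fixed before the data were examined. That rule takes every named gene past the threshold, fills each direction to 10 with the genes of smallest p that had the same sign in all 4 hybridisations, and adds a panel of 14 genes and the 2 members of smallest p of each list.

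Median centring leaves a trend of the cocaine coefficient along the dye effect, whose size differed between arrays. No intensities were used here, so a within-array loess against intensity could not be made. Each scan was therefore also fitted by loess (span 0.3, 4 iterations) along a dye profile, the mean Cy5 over Cy3 log ratio of the 4 Agilent scans with both orientations balanced. Treatment cancels from that profile, and its value was high for ribosomal protein probes (median 1.91) and low for olfactory receptor probes (median -0.97). This second normalization was chosen after the data and the results under the median centring had been seen, and 8 ways of normalizing were tried in all. It was for a time taken as the primary version after both sets of results had been seen, and the centring fixed beforehand was then kept as primary. Values from it are called dye-profile values and stand beside the centred ones; the closing section gives the counts under each way.

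The steps were tested on simulated scans, in 5 simulations of 200 changed genes among 31334. Each scan had a straight-line dye trend fitted to the real scan, and each gene's noise was drawn independently with limma's spread in dye-profile values. With median centring, 100% of 4-fold, 55.5% of 2-fold and 4.2% of 1.5-fold changes were recovered, with 4.8 false calls on average. These shares may be too high for the real data, since the simulated spread was already drawn towards that of all genes. In dye-profile values 100% of simulated 4-fold changes were recovered too. Yet in the real dye-profile values Prdm8, at -2.17, had a limma adjusted p of 0.67. A list of immediate early genes shifted by -0.3 passed camera in 5 of 5 simulations under either normalization. Its mean recovered median was -0.2 after centring and -0.31 in dye-profile values, and 1 other list passed on average after centring against 0 in dye-profile values. The simulated genes were not correlated. The correlation estimated in the real centred values was 0.442 for immediate early genes, 0.868 for heat shock genes and -0.05 for cortical markers. The simulations therefore cannot show how often camera errs on correlated lists.

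Alternatives included no dye term, each scanner alone, all scans with the hybridisation as a random block, other scalings, single probes, filters, other statistics and thresholds, and leaving out each hybridisation in turn. With arrays, the number of hybridisations limits the precision. Limma p-values and standard errors rest on the spread between 4 pairs of mice, with each gene's variance drawn towards that of all genes. After centring this took 15.9 prior against 2 residual degrees of freedom. Camera p-values at the preset correlation compare the genes of a list with the other genes, and do not measure a spread between mice. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom. Its p-values then rise even for a list whose genes are not correlated. The smallest two-sided sign-flip p of 4 hybridisations is 0.125.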

Results

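Gene expression in the nucleus accumbens was compared between mice given cocaine at 15 mg per kg and mice given saline during a short conditioned place preference procedure. Each of 4 hybridisations set 1 cocaine mouse directly against 1 saline mouse, 2 with cocaine in Cy5 and 2 with saline in Cy5. The question was which genes and which groups of genes differ after the cocaine procedure. Of 31334 genes tested, 19087 had a symbol. Ratios are log2 of cocaine over saline, a direction that is likely but not stated in the labels, and errors are limma standard errors over n = 4 hybridisations.

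Of the 7 genes that fell with cocaine 5 had a symbol, and 3 of these, Tbr1, Nrn1 and Neurod6, are on the list of cortical projection neuron markers. Tbr1, a T-box factor of deep-layer cortical neurons, fell by 1.45 ± 0.18 on the log2 scale. Nrn1, which encodes neuritin, fell by 1.71 ± 0.24. Neurod6, a helix-loop-helix factor of pyramidal neurons, fell by 1.13 ± 0.19. Prdm8, a repressor active in developing cortex, fell by 2.14 ± 0.33, and Prss12, which encodes the protease neurotrypsin, fell by 1.96 ± 0.28. Their limma adjusted p-values were 0.00602, 0.0143, 0.0375, 0.0199 and 0.0143 in that order, and each was lower in 4 of 4 hybridisations.

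The next genes by p in that direction that were lower in 4 of 4 centred hybridisations, none past the threshold, were Cck at -1.13 ± 0.21, Nr4a2 at -1.16 ± 0.22, Cbln2 at -1.14 ± 0.21, Smim43 at -1.32 ± 0.26 and Rspo2 at -0.92 ± 0.19. Cck encodes cholecystokinin and Nr4a2 an orphan nuclear receptor. Their limma adjusted p-values lay between 0.0617 and 0.129. No named gene passed in the other direction. The 10 genes filled in there were Chtf8, Galnt15, Nt5c3b, Nepn, Cep85, Olfr339, Ypel2, 6430604M11Rik, Crybg2 and Nprl3, with log2 ratios between 0.51 and 0.75 and limma adjusted p-values between 0.212 and 0.69. These are not the strongest differences, since the rule leaves out genes whose centred signs differ between hybridisations. On the higher side it left out 4 named genes of smaller p than Chtf8, the first filled in, chosen here after their values were seen. These were Upb1 at 1.08 ± 0.19, Gm31251 at 0.91 ± 0.17, Cstad at 0.90 ± 0.18 and Tedc1 at 0.90 ± 0.19, with limma adjusted p-values between 0.0556 and 0.139. Further genes left out, such as Dlk1 and Ppp1r1b, had a smaller p than most of the 10 filled in. On the lower side it left out 2 of smaller p than Cck, the first filled in there. These were Prps1l1 at -0.997 ± 0.173 (limma adjusted p = 0.0556) and Nxph3 at -1.60 ± 0.29 (0.0617).

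**Figure D1:**
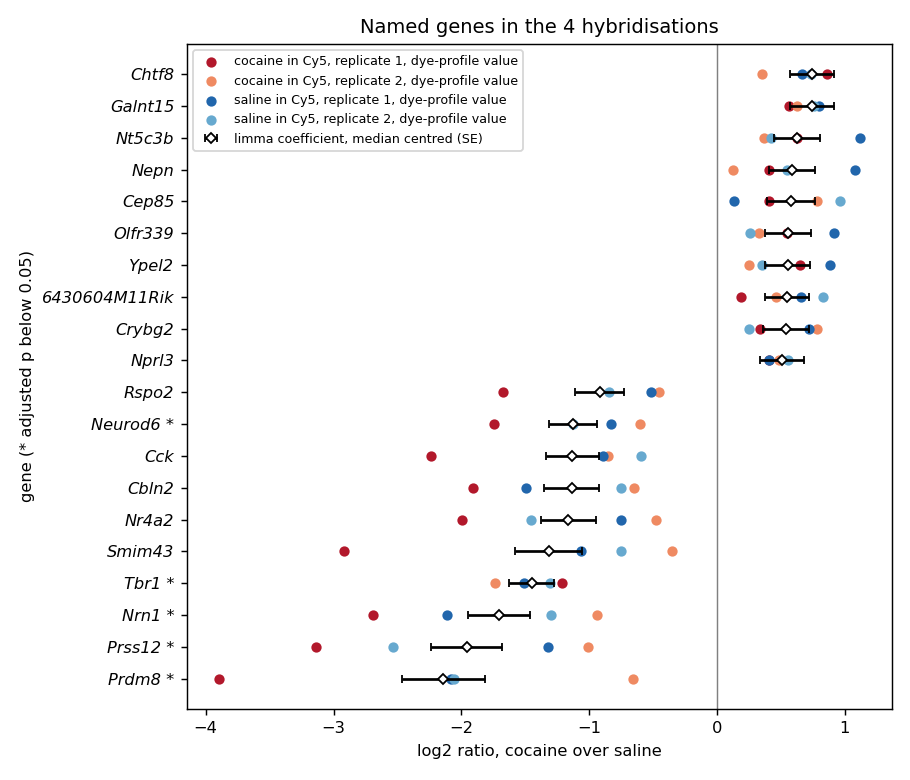
Log2 ratio of cocaine over saline (horizontal axis) of the 20 genes named by direction (vertical axis). Filled points are the 4 hybridisations after fitting along the dye profile, open diamonds with bars are the limma coefficient and its standard error after median centring, and stars mark the 5 genes past adjusted p 0.05. Prdm8 spread from -3.90 to -0.66, whereas Tbr1 lay between -1.74 and -1.21.

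In all, 8 genes passed limma's adjusted p of 0.05, 1 higher and 7 lower. The other 3 were array features without a symbol, which may be control spots. In dye-profile values 0 genes passed (lowest adjusted p 0.592), with 2272 genes at an unadjusted p below 0.05 against 1894 after centring. The dye-profile ratio was -1.44 ± 0.13 for Tbr1 and -1.76 ± 0.31 for Nrn1. Without 1 hybridisation the number of genes changed between cocaine and saline rose, to 288 without cocaine in Cy5 replicate 1, 148 without cocaine in Cy5 replicate 2, 91 without saline in Cy5 replicate 1 and 66 without saline in Cy5 replicate 2, each with all 8 among them, and limma then took the spread to be equal for every gene.

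Among the 21 gene lists, 7 shifted by camera, 4 towards lower and 3 towards higher values in cocaine mice. With an estimated correlation 0 lists passed, and fry passed 0 after centring and 2 in dye-profile values. The version with an estimated correlation has 2 residual degrees of freedom, with which a list can hardly pass. For cortical markers the estimated correlation was -0.05, below the preset 0.01, and the list still did not pass. That 0 therefore does not separate correlation between genes from too few hybridisations. The dye-profile values gave 8 shifted lists, of which 6 were shared in the same direction. Without saline in Cy5 replicate 1 the number of gene lists shifted between cocaine and saline was 4.

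Markers of cortical projection neurons fell as a group, with 11 of 14 measured members below 0, a median of -0.24 and a mean of -0.53 (camera adjusted p = 4.69e-13; adjusted p = 0.311 with an estimated correlation). Tbr1, Nrn1 and Neurod6 passed over all genes, and 6 members passed when adjusted over the list alone, all lower. Those further 3 were Ccn2 at -1.39 ± 0.29, Neurod2 at -0.82 ± 0.18 and Slc17a7 at -0.52 ± 0.18, the last encoding the vesicular glutamate transporter of cortical neurons. Lamp5, at 0.38 ± 0.18, went the other way without passing. In dye-profile values the list's median was -0.22 (camera adjusted p = 6.16e-06; adjusted p = 0.644 with an estimated correlation; fry adjusted p = 0.0155) and was below 0 in 4 of 4 hybridisations.

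Immediate early genes, which neurons transcribe within minutes of being driven, fell as a group beside these cortical markers. Their median was -0.19, with 18 of 24 members below 0 (camera adjusted p = 6.78e-05; adjusted p = 0.892 with an estimated correlation). The centred list medians per hybridisation were 0.83 and 1.16 with cocaine in Cy5 but -0.78 and -1.47 with saline in Cy5. Only Nr4a2 passed when adjusted over the list alone, at -1.16 ± 0.22, and 0 members passed over all genes. Egr1 stood at -0.32 ± 0.19, Npas4 at -0.30 ± 0.19, Arc at -0.29 ± 0.21, Nptx2 at -0.36 ± 0.17, Fos at -0.19 ± 0.17 and Fosb at -0.07 ± 0.19. In dye-profile values the median was -0.33 (camera adjusted p = 2.35e-09; adjusted p = 0.644 with an estimated correlation), 16 members were lower in 4 of 4 hybridisations and 12 passed when adjusted over the list alone, Egr1 at -0.51 ± 0.11 and Arc at -0.51 ± 0.16 among them. Over all genes, 19.06% had the same sign in 4 of 4 hybridisations in dye-profile values. The shared profile ties the 2 orientations together there, so 4 of 4 is not 4 independent agreements, for genes or for list medians. Without saline in Cy5 replicate 2 the centred immediate early genes median log2 was -0.04 and the list no longer passed (camera adjusted p = 0.217).

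Heat shock and unfolded protein response genes also fell, with 16 of 18 members below 0 and a median of -0.15 (camera adjusted p = 0.000132; adjusted p = 0.892 with an estimated correlation). The centred list medians per hybridisation were 0.575 and 1.35 with cocaine in Cy5 but -1.04 and -1.46 with saline in Cy5. Sdf2l1, a partner of endoplasmic reticulum chaperones, stood at -0.54 ± 0.20. The inducible chaperone Hspa1a stood at -0.44 ± 0.18, with 1 of the 4 Hspa1a probes above 0. None of the members passed over all genes or when adjusted over the list alone (0 of 18), while 8 passed over the list alone in dye-profile values. There the median was -0.30 (camera adjusted p = 5.25e-10; adjusted p = 0.644 with an estimated correlation) and 14 members were lower in 4 of 4 hybridisations. The share of all genes with the same sign in 4 of 4 was 19.06% in these values. The centred heat shock and unfolded protein response median log2 was 0.02 without cocaine in Cy5 replicate 1 (camera adjusted p = 0.836) and -0.04 without saline in Cy5 replicate 2 (0.0896).

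Oligodendrocyte and myelin markers fell, with 13 of 19 members below 0 and a median of -0.08 (camera adjusted p = 0.00639; adjusted p = 0.892 with an estimated correlation). Aspa, at -0.39 ± 0.19, and Trf, at -0.45 ± 0.24, had the smallest p, and 0 members passed when adjusted over the list alone. In dye-profile values the median was -0.24 (camera adjusted p = 0.00123; adjusted p = 0.758 with an estimated correlation). The dye-profile medians were -0.48 and -0.38 in replicate 1 of cocaine in Cy5 and of saline in Cy5, and 0.10 and -0.11 in replicate 2 of each, and without cocaine in Cy5 replicate 1 the centred oligodendrocyte and myelin markers median log2 was 0.10 (camera adjusted p = 0.863). Without saline in Cy5 replicate 1 it was -0.09, and the list no longer passed (0.145).

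**Figure D2:**
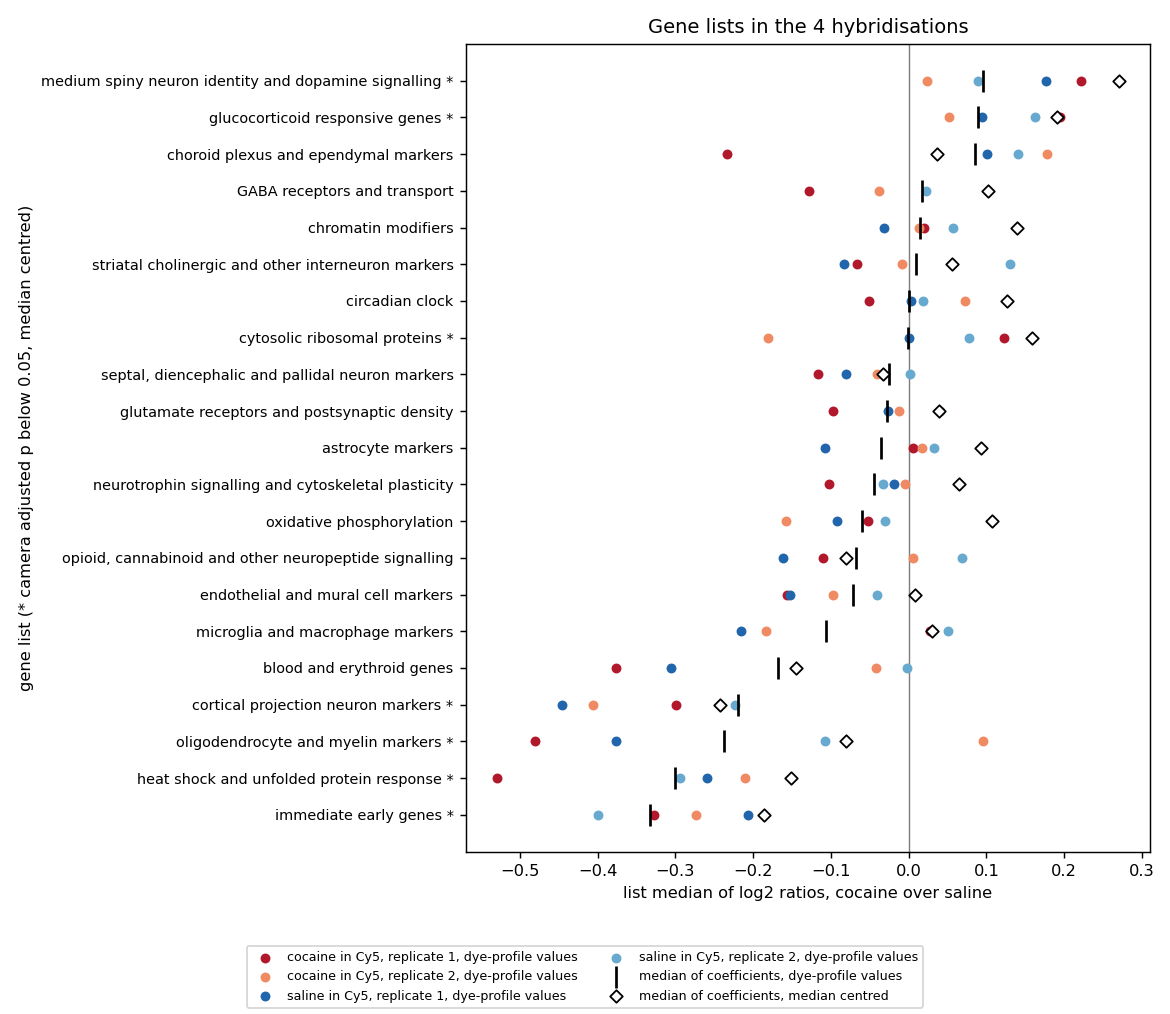
Median log2 ratio of cocaine over saline (horizontal axis) of each of the 21 gene lists (vertical axis). Filled points are the 4 hybridisations and the black bar the median of limma coefficients in dye-profile values, open diamonds are the median of coefficients after median centring, and stars mark the 7 lists past camera's adjusted p of 0.05 after centring. Immediate early genes lay below 0 in 4 of 4 hybridisations, between -0.40 and -0.21.

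Genes of medium spiny neurons, the projection neurons of the striatum, and of dopamine signalling were higher as a group. All 26 measured members had coefficients above 0, with a median of 0.27 (camera adjusted p = 3.5e-08; adjusted p = 0.892 with an estimated correlation), yet 0 passed when adjusted over the list alone and 0 had the same sign in all 4 centred hybridisations. Ppp1r1b, which encodes DARPP-32, stood at 0.69 ± 0.19, Adcy5 at 0.61 ± 0.20, Pdyn at 0.50 ± 0.17, Penk at 0.37 ± 0.18, Drd1 at 0.24 ± 0.18, Drd2 at 0.21 ± 0.19 and Tac1 at 0.09 ± 0.17. The median was 0.10 in dye-profile values (camera adjusted p = 0.000199, adjusted p = 0.709 with an estimated correlation, fry adjusted p = 0.381). There 8 of 26 members were higher in 4 of 4 hybridisations, where 19.06% of all genes had the same sign in 4 of 4.

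Glucocorticoid responsive genes were higher too, with 0 of 15 members below 0 and a median of 0.19 (camera adjusted p = 0.000842; adjusted p = 0.892 with an estimated correlation). Sult1a1 stood at 0.51 ± 0.18 and Plin4 at 0.42 ± 0.17, and 0 members passed when adjusted over the list alone. The dye-profile median was 0.09 (camera adjusted p = 0.0227; adjusted p = 0.644 with an estimated correlation; fry adjusted p = 0.0483). Cytosolic ribosomal protein genes had a median of 0.16 over 60 members (camera adjusted p = 6.78e-05; adjusted p = 0.892 with an estimated correlation), among them Rpl4 at 0.36 ± 0.19 and Rpl11 at 0.30 ± 0.18. Of these members 0 passed when adjusted over the list alone, and their median was -0.001 in dye-profile values (camera adjusted p = 0.69). Without saline in Cy5 replicate 1 neither list passed, with a glucocorticoid responsive genes median log2 of 0.14 (camera adjusted p = 0.0591) and a cytosolic ribosomal proteins median log2 of 0.08 (0.184).

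The other 14 lists did not pass after centring. Blood and erythroid genes (median -0.15, camera adjusted p = 0.064) and endothelial and mural cell markers (0.01, 0.582) passed in dye-profile values, with medians of -0.17 and -0.07 and camera adjusted p-values of 0.0191 and 0.0319. With an estimated correlation these adjusted p-values were 0.644 and 0.709, and by fry 0.381 and 0.333. As for oligodendrocyte markers, the fall of the blood and erythroid list lay mainly in replicate 1. Its dye-profile medians were -0.38 (cocaine in Cy5) and -0.31 (saline in Cy5) there, and -0.04 and -0.002 in replicate 2. Hbb-bt stood at -0.23 ± 0.21, S100a9 at -0.30 ± 0.17, Kdr at -0.30 ± 0.17 and Esam at 0.18 ± 0.18. Medians were 0.11 for oxidative phosphorylation (Cyc1 at 0.43 ± 0.18, Atp5b at 0.33 ± 0.20), 0.13 for the circadian clock (Ciart at 0.49 ± 0.17, Dbp at 0.48 ± 0.17), 0.14 for chromatin modifiers (Hdac7 at 0.41 ± 0.18, Hdac3 at 0.33 ± 0.18) and 0.10 for GABA receptors and transport (Gabrg1 at 0.44 ± 0.17, Gabra4 at 0.41 ± 0.18). They were 0.04 for glutamate receptors and the postsynaptic density (Nrgn at -0.47 ± 0.20, Gria1 at 0.43 ± 0.19), 0.07 for neurotrophin signalling (Ntrk3 at 0.39 ± 0.20, Bdnf at -0.36 ± 0.17, Ntrk2 at 0.17 ± 0.18, Creb1 at -0.06 ± 0.17 with 1 of 3 probes above 0) and -0.08 for neuropeptide signalling (Oprk1 at 0.55 ± 0.19, Cartpt at 0.43 ± 0.20).

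Among the markers of other cells, medians were 0.09 for astrocytes (Aldh1l1 at 0.33 ± 0.18, Aldoc at 0.23 ± 0.18), 0.03 for microglia (Trem2 at 0.23 ± 0.17, Laptm5 at 0.16 ± 0.17 with probes of opposite sign), 0.04 for choroid plexus and ependyma (Clic6 at 0.37 ± 0.17, Col8a1 at -0.33 ± 0.17), -0.03 for septal, diencephalic and pallidal neurons (Dlk1 at 0.67 ± 0.18, Avp at -0.44 ± 0.18) and 0.06 for striatal interneurons (Pvalb at -0.74 ± 0.26, Slc5a7 at 0.25 ± 0.17). The camera adjusted p-values of these 5 lists lay between 0.129 and 0.883. Camera's direction was downward despite a median above 0 for the glutamate, endothelial, choroid plexus and interneuron lists. In dye-profile values the median was below 0 for the glutamate, neurotrophin, oxidative phosphorylation, astrocyte, microglia and endothelial lists, against above 0 after centring.

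Some of these 14 lists passed camera when 1 hybridisation was left out. Without cocaine in Cy5 replicate 1 these were the chromatin modifiers median log2 of 0.20 (camera adjusted p = 0.04), the circadian clock median log2 of 0.23 (0.03) and the oxidative phosphorylation median log2 of 0.17 (0.00795). Without saline in Cy5 replicate 2 the oxidative phosphorylation list stood at 0.19 (0.00451). Without cocaine in Cy5 replicate 2 the blood and erythroid genes median log2 was -0.25 (0.0033) and the opioid, cannabinoid and other neuropeptide signalling median log2 was -0.05 (0.0367).

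The dye was the larger source of variation in these ratios. A dye effect passed limma's adjusted p of 0.05 for 24406 of 31334 genes, 10819 towards Cy5 and 13587 towards Cy3, with a median size of 0.749 on the log2 scale against 0.133 for the cocaine coefficient. Between hybridisations, the centred ratios correlated across genes at r = 0.824 and 0.865 within an orientation and at -0.888 to -0.752 between orientations. In dye-profile values r lay between -0.017 and 0.133 over all 6 pairs. The dye profile is a mean over these same hybridisations, so removing it can raise r between orientations and lower it within an orientation, and 0 is not the value without a treatment effect. For the same reason the numbers of genes with the same sign in all 4 hybridisations are compared with other splits that are balanced over the dyes, a comparison chosen after the results were seen. In dye-profile values there were 5971 such genes (19.1%) for the real labels, and 3758 and 3733 in the other 2 such splits, which are too few for a test. After centring there were 578 (1.84%), since there the dye effect gives opposite signs between orientations. Genes are not independent replicates, so no p-value is given. After centring, the cocaine coefficient had a median of -0.05 in the tenth of genes with the lowest dye profile and of 0.17 in the tenth with the highest.

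**Figure D3:**
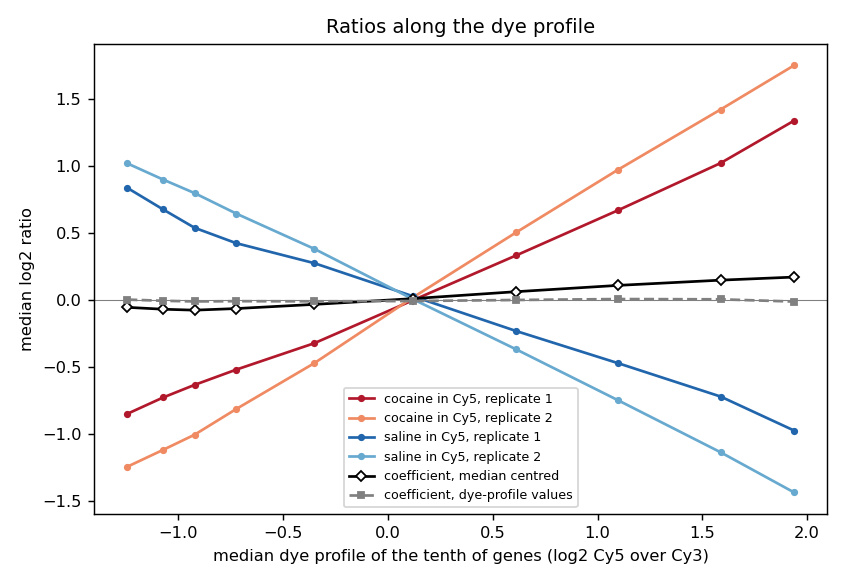
Median log2 ratio (vertical axis) in 10 equal groups of genes ordered by the dye profile, the mean log2 Cy5 over Cy3 ratio (horizontal axis), for each hybridisation after centring. The cocaine in Cy5 lines rise to 1.34 and 1.76 and the saline in Cy5 lines fall to -0.97 and -1.43, and the cocaine coefficient rises to 0.17 after centring and stays within 0.01 of 0 in dye-profile values.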

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

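The tests of explanations in this part were chosen after the results had been seen, apart from the test on the separate cortical list, whose members and prediction were written before their values were seen.

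Values that stood apart from the other 3 hybridisations in dye-profile values were found for Hdac7, where saline in Cy5 replicate 2 stood at 0.77 against 0.15 to 0.23 (gap over range 0.88), and for S100a9, where the same hybridisation stood at -0.57 against -0.19 to -0.15 (0.91). Of 92 sets of 4 values tested, 2 stood apart, and chance gives about 4.6.

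Cortical projection neuron markers were lower with cocaine. Dye bias would give opposite signs in the 2 orientations. The centred values, from which no dye effect was removed, had a median of -0.61 with cocaine in Cy5 and of -0.55 with saline in Cy5. In dye-profile values these medians were -0.352 and -0.334. There the near-equal values are built in, because the profile is a mean over the same hybridisations. Only the centred medians bear on dye bias. Each of the other lists that passed after centring had centred medians above 0 with cocaine in Cy5 and below 0 with saline in Cy5. Their shifts rest on the balance of the 2 orientations. A candidate explanation is less cortical tissue in the cocaine samples. Of 15 further cortical pyramidal neuron genes, 0 of them in another list, 9 lay below 0 after centring, with a median of -0.11. That was the 0.07 percentile of 10000 random lists matched on the dye profile, which do not carry the correlation between genes of a list. Vsnl1 stood at -0.63, Ccn3 at -0.67 and Nptx1 at -0.35, but Gnb4 at 0.29, Dkk3 at 0.28 and Tle4 at 0.25. None of the 15 passed limma's adjusted p. Many of these genes have some expression in the accumbens, so a change within accumbens cells stays open. Splits of the 4 pairs, the real one included, were too few (7) for a share under 0.05. The split that follows the dye orientation was left out. The real labels gave 8 genes and the highest other split 9, and 2 of the 7 splits, the real one included, gave as many as the real one. For lists the real labels gave 7 and the highest other split 8, and 3 of the 7 splits gave as many. In dye-profile values the real labels gave 8 lists and the highest other split 7, and 0 genes passed limma under any of the 7 splits. Genes at an unadjusted p below 0.05 numbered 2272 under the real labels and at most 2159 under another split. Those highest other splits were not balanced over the dyes. The other 2 balanced splits gave 2 lists each, and 1210 and 1102 such genes. After centring the balanced splits gave 6 and 5 lists, and 0 and 9 genes passed.

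Immediate early and heat shock genes were lower with cocaine. Both lists have a high dye profile (medians 1.43 and 1.74), where the trend left by the centring lies above 0, yet their medians lay further below 0 once that trend was removed, at -0.333 and -0.3. Less cortical tissue cannot be told apart from an effect in accumbens cells. Genes expressed in both tissues would fall less than cortical markers. The centred list means lay 0.359 (SE 0.184) and 0.353 (SE 0.181) above that of the cortical markers, which either explanation allows. These SEs are taken over the member genes of the lists, which are not independent, and not over hybridisations. The order depends on the measure. In dye-profile values the means kept it, at -0.288 and -0.323 against -0.56 for cortical markers. The dye-profile medians reversed it, at -0.333 and -0.3 against -0.22. Nr4a2, the largest fall among the immediate early genes, is also a marker of deep cortical layers. The treatment stays open as an untested explanation.

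Ribosomal protein and medium spiny neuron genes were higher with cocaine after centring. For ribosomal proteins the trend along the dye profile is a candidate explanation, since the median was -0.001 in dye-profile values. Medium spiny neuron genes lay higher than most random lists matched on the dye profile. Their median lay at the 99.9 percentile after centring and at the 99.7 percentile in dye-profile values, where it was 0.095 and above 0 in 4 of 4 hybridisations. For ribosomal proteins these percentiles were 68.4 and 57.5. For glucocorticoid responsive genes, also higher after centring, they were 98.1 and 98.6. The criterion for medium spiny neuron genes was changed repeatedly after its values had been seen, and an earlier version left the trend open. No verdict on the trend as their whole cause is therefore drawn. Random lists do not carry the correlation between genes of a list, and with an estimated correlation the medium spiny neuron list did not pass in dye-profile values (adjusted p = 0.709; fry adjusted p = 0.381). A larger share of accumbens tissue and a treatment effect both stay open for these.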

How the results depend on the processing

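The dye-profile settings, the tests without dye term beside another scaling, the restriction to named genes and that to the upper part of the dye profile were chosen after seeing the data. Against 8 genes changed between cocaine and saline (1 higher, 7 lower), the count was 0 without a dye term, in Axon scans, after scaling to a common median absolute deviation, after quantile normalization and with the ordinary statistic. It was 1 with all 8 scans and a random block, 1 against a fold of 1.2, 5 without the 25% of genes with the largest scanner disagreement, 16 with a robust prior, 20 in Agilent scans, 25 at adjusted p below 0.10, 97 (19 higher, 78 lower) without centring and 120 with single probes. Along the dye profile it was 0 by loess, straight line, wider span and all 8 scans, with or without the dye term, and 0 as deposited or scaled without the dye term. Among named genes alone it was 25 and in the upper part of the dye profile 148. Leaving out 1 hybridisation gave 66 to 288. The counts of 97, 120, 148 and 66 to 288 came with an infinite prior, under which every gene has the same variance. Read as Cy5 over Cy3 the count was 24406, and 1 orientation alone gave 20316 (cocaine in Cy5) and 17710 (saline in Cy5), which hold the dye effect by construction. The 5 named genes kept their direction under all 10 alternatives run for them, with Prdm8 between -2.975 and -1.305 and Tbr1 between -1.592 and -1.307. They passed in 7: Agilent scans, and, under that infinite prior, no centring, single probes and each hybridisation left out. They did not pass without a dye term, in Axon scans or along the dye profile. The common scaling, quantile normalization, ordinary statistic, random block and fold of 1.2 were not among the 10.

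Gene lists shifted between cocaine and saline numbered 0 with an estimated correlation, 0 by fry, 12 read as Cy5 over Cy3 and 4 to 9 with 1 hybridisation left out (4 without saline in Cy5 replicate 1), against 7. Read as Cy5 over Cy3, medians turned to 0.94 for immediate early genes, 1.17 for heat shock genes and 0.32 for oligodendrocyte markers, and the last lay between -0.295 and 0.097 with 1 hybridisation left out. The count of genes with a dye effect was 3912 in Axon scans and 19777 to 23493 with 1 hybridisation left out, against 24406, and without centring 3838 were towards Cy5 and 19957 towards Cy3. The agreement between hybridisations, the mean r of opposite orientations, was -0.82 and became -0.466 in Axon scans, -0.928 in Agilent scans, -0.733 after scaling and 0.042 along the dye profile, where 0 is not the value without a treatment effect because the profile comes from the same hybridisations. Apart from what these settings remove by construction, the cause was not tested. Of 441 list medians under alternatives, 319 kept direction and side of the threshold, as did 655 of 710 named gene ratios. No other pairing was run, since each ratio is already a difference within a pair of mice. Signal over background was not used here, so dim probes could not be left out by it. In dye-profile values, repeated spots of a probe differed within a hybridisation by a median SD of 0.188 over 38 probes. These SDs ran from 0.031 for Chgb to 0.444 for Anxa8.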

Other observations

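The genes in this part were chosen after their values were seen. In dye-profile values, 44 named genes had a log2 ratio at least 0.35 from 0 with the same sign in all 4 hybridisations, 28 lower and 16 higher with cocaine. The other 2 splits balanced over the dyes gave 9 and 10 such genes. The 44 include the 5 named genes that passed after centring, Tbr1, Prss12, Nrn1, Prdm8 and Neurod6. Other lower ones included Nxph3 at -1.77 ± 0.35, which encodes a neurexophilin of deep cortical layers, Cort at -0.46 ± 0.10, which encodes the peptide cortistatin, Klf10 at -0.46 ± 0.10, Midn at -0.67 ± 0.13, Cadps2 at -0.56 ± 0.13, Tmem40 at -0.84 ± 0.12 and Pcp4 at -0.53 ± 0.10. The higher ones included Upb1 at 0.96 ± 0.14 and Tedc1 at 0.96 ± 0.14, Cenpb at 0.59 ± 0.11, Rasal1 at 0.65 ± 0.16 and Gucy1a1, a subunit of the nitric oxide receptor, at 0.50 ± 0.11. These 12 others did not pass limma's adjusted p in either normalization.

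Single members of lists that did not shift also stood out when adjusted over the list alone. Cck, in the neuropeptide list, had an adjusted p of 0.0006 and a ratio of -1.13 ± 0.21, and Dlk1, in the septal, diencephalic and pallidal list, 0.0307 and 0.67 ± 0.18. Each of these lists had 1 member that passed in this way. In the same lists Slc17a6 stood at -0.59 ± 0.25, Th at 0.40 ± 0.20, Oprd1 at 0.46 ± 0.23 and Sst at -0.24 ± 0.19, none of them past the threshold over the list alone.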
